A study of Oryza sativa with 6 samples.

How the data were processed

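The study measured RNA of rice shoots on Affymetrix GeneChip whole-transcript arrays. Per the labels' protocols, total RNA was isolated with a plant and fungal spin-column kit and biotin-labelled with the GeneChip WT terminal labelling kit. The deposited values are on a log2 scale, already normalized between arrays by the authors, as judged from their range and matched medians. Affymetrix Expression Console is named in the submitters' processing notes, and its version, algorithm and settings are not given in the sources used here. A normalization that assumes most probes unchanged would hide a shift common to all probes. Background correction and detection calls were not used here, so dim probes stayed in.

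Groups and replicate numbers came from the sample labels: 2 arrays at 0 h, 2 at 6 h and 2 at 24 h. Each probe was tested with limma 3.58.1 in R 4.3.3, with all 6 arrays in 1 fit, group as the only term and the spread pooled over 3 residual and 2.58 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all 41770 probes in each contrast, with a threshold of 0.05. Errors of changes are limma's standard errors. The limma and list tests, the alternatives listed at the end, the words that define the gene lists and the rule for named genes were fixed before the data were examined. Added after the data were seen were an adjusted p of 0.10, the count of identical probes once, the simulated covariance under each alternative, the screen of symbol families, the tests of time of day and handling, and loci known only by placeholder.

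Genes came from the platform annotation, updated through a RefSeq gene table of the assembly ASM3414082v1, used for names alone. Of the probes, 15299 had exactly 1 gene, 436 several and 26035 none listed here, and 15298 of the first matched the RefSeq table. A symbol other than a locus placeholder was known for 1944 genes. Genes named are the 10 highest and 10 lowest changes among calls with 1 gene name and groups that do not overlap, up to 5 of the smallest p as not passing where fewer passed, up to 4 members per list and every clock gene. A gene name was read as a symbol that is not a placeholder. Loci known only by placeholder are added to the rule, and the genes drawn per array, KSL4, PSB28 and RBCS-C were chosen after their values were seen.

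The 25 gene lists had been fixed as words in symbols or product descriptions. The annotation held no descriptions, so the lists were rewritten as symbols after the annotation was seen and before any contrast was computed. They hold 361 genes, and 21 lists had the 3 genes needed for a test. The pathogenesis-related list held PBZ1 and otherwise only genes with a chitinase symbol, so it does not stand for such proteins in general. Lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and 1 probe per gene, the one with the highest mean, over 14662 genes. P-values were adjusted over the lists of a contrast. No list call at an adjusted p of 0.05 held with an estimated correlation, a version that seldom called a simulated shift, as given below.

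The steps were tested on simulated data with the real means and residual variances and 200 changed probes. For 6 h against 0 h, over 41770 probes with 6 arrays, 68.4% of changes of log2 2 were recovered, 48.2% of log2 1.5, 23% of log2 1 and 0% of log2 0.5. With 5 arrays no change of these sizes was recovered. Camera over 14662 genes called a diterpenoid list shifted by 0.7 in 100% of 20 draws with the preset correlation and in 5% with an estimated one, for 6 h against 0 h. For 24 h against 0 h and for 24 h against 6 h these were 100% and 0%. A call lost with an estimated correlation therefore does not by itself argue against a list. Nor does it by itself show that the genes of a list are correlated. For the diterpenoid list the estimate was 0.0116, close to the preset 0.01. Its unadjusted camera p at 6 h still went from 8.3e-06 to 0.0213. Some lists had higher estimates, such as 0.318 for WRKY.

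The alternatives were quantile normalization, median centring, a filter on dim probes, a trended and robust prior, a fit of the compared groups alone, the replicate number as a block, each array left out, a 2-fold minimum, averaging of the probes of a gene, and a count with no test. Overlap between the comparisons with 0 h was set beside 100 simulations of unchanged groups. Symbol families were screened with camera. Figures were drawn with matplotlib 3.10.9.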

Results

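Shoots of control rice plants and of plants given a suspension of Rhodotorula mucilaginosa, a pigmented basidiomycete yeast, were profiled on 6 arrays. The 3 groups were shoots taken at 0 h, which served as the control, at 6 h and at 24 h, with 2 arrays each. The values are log2 signals of 41770 probes, with array medians from 5.98 to 6.05. Replicate arrays correlated across probes with r = 0.992 at 0 h, 0.987 at 6 h and 0.992 at 24 h, and 221, 604 and 233 probes lay at least 2-fold apart within these pairs. Arrays of different groups correlated with r from 0.983 to 0.988. Genes are not independent replicates in these correlations, and the number of arrays limits the precision of every value. The labels do not say that the 2 arrays of a group came from separate plants, so p-values measure only the spread between these samples. Plants kept for 6 h or 24 h without yeast were not analysed here, so treatment and elapsed time come together in both comparisons with 0 h.

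The first comparison asked which transcripts differed in the shoot 6 h after the yeast was given. As lists, genes for making diterpenoid phytoalexins, antimicrobial compounds of rice, rose, and genes of photosynthesis and of the circadian clock fell, with 3 of 8, 2 of 7 and 2 of 4 genes past the threshold over all probes. These list calls were made by camera with a preset correlation and were lost with an estimated one (adjusted p = 0.324, 0.372 and 0.324 with an estimated correlation). The estimated correlations were 0.0116, 0.114 and -0.167, against the preset 0.01. For the diterpenoid and clock lists a correlation well above the preset one therefore does not account for the loss. CYP701A8, a cytochrome P450 of diterpenoid synthesis, rose 3.48-fold (log2 change 1.80 ± 0.11, SE, 2 arrays per group, adjusted p = 0.0108). CPS2, the copalyl diphosphate synthase that starts the phytocassane branch, rose by 1.24 ± 0.10 (adjusted p = 0.0135). CCA1, a morning transcription factor of the clock, fell by 0.95 on the log2 scale (SE 0.12, adjusted p = 0.0311), and CAB1R, a chlorophyll a/b-binding protein, fell by 1.11 (SE 0.13, adjusted p = 0.0266).

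In the diterpenoid list all 8 measured genes were higher at 6 h, with a mean log2 change of 0.81 (adjusted p = 0.000175 by camera, adjusted p = 0.324 with an estimated correlation). Of these, 3 passed over all probes, namely CYP701A8, CPS2 and CYP76M5 at 0.97 ± 0.15, and 6 passed when adjusted over the list alone. KSL4, a diterpene synthase of the momilactone branch, had a log2 change of 1.33 ± 0.39 and did not pass over all probes (adjusted p = 0.189). The photosynthesis list fell by a mean of 0.50 over 7 genes (adjusted p = 0.00098, adjusted p = 0.372 with an estimated correlation). CAB1R and LHCP, another antenna protein gene (log2 change -0.71 ± 0.10), passed over all probes, and 4 genes passed when adjusted over the list alone. PSB28 and RBCS-C, the latter a small subunit of Rubisco, had log2 changes of 0.05 and -0.17 that did not pass. All 4 measured clock genes were lower, with a mean of -0.66 (adjusted p = 0.00103, adjusted p = 0.324 with an estimated correlation). CCA1 and the pseudo-response regulator PRR37 (-0.82 ± 0.11) passed over all probes, 3 passed when adjusted over the list alone, and PCL1 and GI had values of -0.67 and -0.19 without passing over all probes.

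Single genes of hormone, metal and cell wall biology were also among the calls at 6 h. The largest rise of a gene with a symbol was that of IAA14, an Aux/IAA repressor of auxin signalling, with a log2 change of 2.00 ± 0.19 (adjusted p = 0.0168). IAA30 rose by 1.10 ± 0.13 and IAA13 by 0.99 ± 0.10, whereas IAA6 fell by 0.71 (SE 0.10). The auxin list of 41 genes did not pass as a whole (adjusted p = 0.421 by camera), with 4 genes higher and 1 lower when adjusted over the list alone. NAS1 and NAS2, nicotianamine synthases that make a chelator of iron and other metals, rose by 1.16 ± 0.16 and 1.19 ± 0.12, and YSL15, a transporter of iron chelates, rose by 0.73 ± 0.10. The iron list of 21 genes did not pass (adjusted p = 0.324). CKX3, a cytokinin oxidase, rose by 0.82 ± 0.10, the expansin EXPB4 by 0.92 ± 0.11, the germin-like protein GER5 by 1.30 ± 0.15 and LAC19, a laccase, by 1.21 ± 0.11. ABCG32, BGLU8, FTIP7, ERG3 and RIBA2 completed the 10 highest, at log2 changes from 1.24 to 1.52. Among the lowest were the protein kinase CIPK10 at -2.15 ± 0.12, the hexokinase HXK7 at -1.68 ± 0.16, ABA1, which encodes zeaxanthin epoxidase of abscisic acid synthesis, at -1.17 ± 0.16, and the phytosulfokine precursor PSK5 at -1.13 ± 0.15. CAX1b, HAK13, BBD2 and OsC3H54 fell by 1.01 to 1.11 on the log2 scale, PYL11 fell by 0.71 and EXLA1 by 0.80. Of genes known here only by locus, LOC4345968 fell by 2.82 and LOC4331137 rose by 2.53.

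Lists of defence signalling did not pass at 6 h. The camera adjusted p was 0.431 for the 6 WRKY genes, 0.431 for the 12 pathogenesis-related genes, 0.252 for the 21 phenylpropanoid genes, 0.481 for the 24 jasmonate genes and 0.511 for the 4 ethylene synthesis genes. It was 0.541 for the AP2/ERF factors, 0.822 for abscisic acid and dehydration, 0.912 for cytokinin, 0.829 for nitrogen and 0.753 for phosphate starvation. The remaining lists gave 0.926 for heat shock, 0.525 for glutathione S-transferases, 0.137 for expansins and XTH, 0.772 for sugar and starch, 0.753 for ribosomal proteins and 0.142 for cell division. CEBIP, the chitin-binding receptor protein and the lone member measured of its list, had a log2 change of 0.03. Lsi2, the lone root marker measured, had one of 0.10, and neither passed or kept its sign without each array. At 24 h CEBIP was higher by 0.39 against 0 h and by 0.37 against 6 h. Neither of these values passed over all probes. Adjustment over its list of 1 gene changes nothing, so both passed there only at an unadjusted p under 0.05 by limma. Of all probes, 16.8% had such a p at 24 h against 0 h and 14.3% at 24 h against 6 h. The gibberellin list and the class III peroxidase list held 2 genes each, too few for the test, with mean log2 changes of -0.14 and 0.27.

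Over all probes, limma called 699 at 6 h against 0 h, 341 higher and 358 lower, of which 362 changed at least 2-fold. At an unadjusted p under 0.05 by limma there were 6836 probes, and 7007 for 24 h against 0 h. The fit pooled 1 spread over the groups, although differences within the 6 h pair were wider (SD 0.357, against 0.270 at 0 h and 0.274 at 24 h). A gene symbol was known for 77 of them, 49 higher and 28 lower. Leaving out any 1 of the 6 arrays, the controls included, left 0 calls. All 699 kept their sign in every one of these fits, but they were chosen on the same arrays, so this is no independent check. The count was 3369 with a trended and robust prior, 2437 over the brighter probes and 0 with the 2 groups fitted alone.

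**Figure D1:**
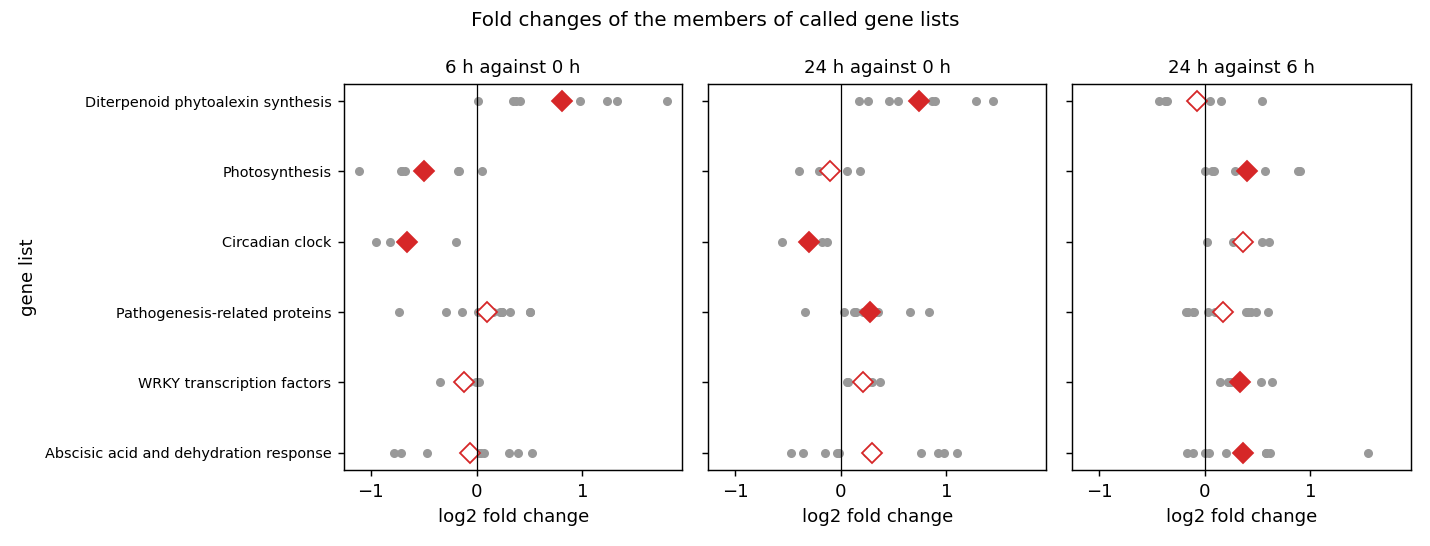
log2 fold changes (x axis) of the measured genes of 6 gene lists (y axis) in the 3 comparisons. Grey points are genes, diamonds are list means, filled where the list passed at an adjusted p of 0.05 by camera. The diterpenoid mean is 0.81 at 6 h and 0.74 at 24 h, and the photosynthesis mean is -0.50 at 6 h and -0.10 at 24 h.

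The second comparison asked which transcripts differed 24 h after the yeast was given. The phytoalexin and pathogenesis-related lists rose by camera with a preset correlation, with 2 of 8 and 0 of 12 genes past the threshold over all probes. Of these lists, the pathogenesis-related one held PBZ1 and otherwise only genes with a chitinase symbol. The estimated correlations of these lists, 0.0116 and -0.036, were close to or below the preset 0.01. Both calls were lost with an estimated correlation (adjusted p = 0.389 and 0.494 with an estimated correlation). That version called a simulated shift of 0.7 in the diterpenoid list in 0% of draws for 24 h against 0 h. LAC19 had the largest rise of a gene with a symbol, 3.09-fold (log2 change 1.63 ± 0.11, adjusted p = 0.0367), followed by the transporter gene ABCG48 at 2.83-fold (SE of the log2 change 0.10, adjusted p = 0.0367) and CYP701A8 at 1.45 ± 0.11 (adjusted p = 0.0389). CHS1, the first enzyme of flavonoid synthesis, fell by 1.28 (SE 0.12, adjusted p = 0.0411).

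All 8 diterpenoid genes were higher at 24 h, with a mean of 0.74 (adjusted p = 5.7e-05 by camera, adjusted p = 0.389 with an estimated correlation). CYP701A8 and CPS2 (0.86 ± 0.10) passed over all probes, and 7 genes passed when adjusted over the list alone. The pathogenesis-related list rose by a mean of 0.27, with 11 of its 12 genes higher (adjusted p = 0.0241, adjusted p = 0.494 with an estimated correlation). None of its members passed over all probes by limma, with 2 passing when adjusted over the list alone, and the largest values were 0.84 ± 0.10 for the chitinase gene Cht-1 (adjusted p = 0.0535) and 0.65 ± 0.13 for PBZ1, a PR10 protein gene (adjusted p = 0.103). The clock list fell by a mean of 0.30 over 4 genes (adjusted p = 0.0467, adjusted p = 0.494 with an estimated correlation), with no member past the threshold over all probes, 1 adjusted over the list alone, and PRR37 at -0.56 ± 0.11 (adjusted p = 0.109). The clock call was lost without either control array (adjusted p = 0.119 and 0.0717) and without either 24 h array (adjusted p = 0.085 and 0.0872). The pathogenesis-related call was lost without control replicate 1 (adjusted p = 0.111) and without 24 h replicate 2 (adjusted p = 0.0775). Over the brighter probes both calls were lost (adjusted p = 0.0516 for each), with means of 0.27 for the pathogenesis-related list and -0.30 for the clock list. The photosynthesis list had a mean of -0.10 (adjusted p = 0.297), and the other lists gave adjusted p from 0.240 to 0.852.

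LEA19, a late embryogenesis abundant protein gene that responds to dehydration, rose by 0.97 ± 0.10 (adjusted p = 0.0449). The dehydrin genes RAB16C and Dhn1 had log2 changes of 1.10 ± 0.13 and 0.92 ± 0.11 and lay just outside the threshold (adjusted p = 0.0535 for both). OsPP2C59, RTUB-1 and RBBI3.3 were the other genes with a symbol that rose, and HCF106, part of the thylakoid protein export machinery, fell by 1.05 on the log2 scale. The locus LOC4327925 rose by 2.59 ± 0.27 at 6 h and by 4.21 ± 0.27 at 24 h. In all, limma called 134 probes at 24 h against 0 h, 74 higher and 60 lower, and 10 of them had a symbol. Leaving out any 1 of the 6 arrays left 0 calls. All 134 kept their sign in every fit, again as probes chosen on the same arrays. The count was 1017 at an adjusted p of 0.10 (447 higher and 570 lower), 3582 with a trended and robust prior (1783 and 1799), 2458 over the brighter probes (1105 and 1353) and 0 with the 2 groups fitted alone, so the larger direction differed between these settings.

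**Figure D2:**
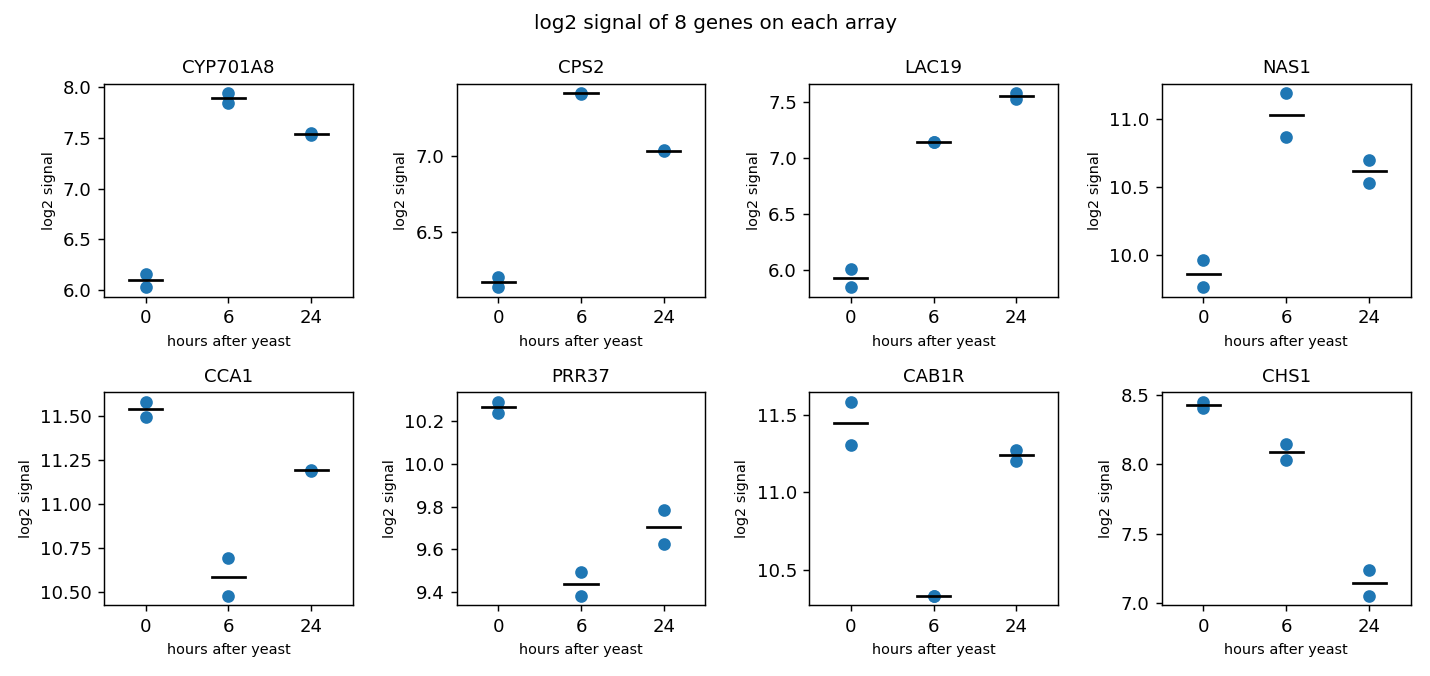
log2 signal (y axis) of 8 named genes on each array against the hours after the yeast was given (x axis, 0, 6 and 24 h, not to scale). Points are arrays and bars are the means of 2 arrays. CYP701A8 lies at 6.03 and 6.16 at 0 h, and between 7.53 and 7.94 on the 4 later arrays.

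The third comparison asked what differed between 24 h and 6 h. The photosynthesis list was higher at 24 h than at 6 h by a mean of 0.40, with 7 of 7 values above 0 (adjusted p = 0.0171 by camera, adjusted p = 0.588 with an estimated correlation). The abscisic acid and dehydration list rose by a mean of 0.36, with 8 of 10 values above 0 (adjusted p = 0.0171, adjusted p = 0.588 with an estimated correlation), and the WRKY list by a mean of 0.33 over 6 genes (adjusted p = 0.0313, adjusted p = 0.588 with an estimated correlation). The estimated correlations of these lists were 0.114, 0.148 and 0.318, against the preset 0.01. No member of these lists passed over all probes, while 3 of 7, 5 of 10 and 1 of 6 genes passed when adjusted over the list alone. The clock list had a mean of 0.36, outside the threshold (adjusted p = 0.0547), the pathogenesis-related list one of 0.18 (adjusted p = 0.197) and the diterpenoid list one of -0.07 (adjusted p = 0.620). No gene with a symbol passed over all probes. ABA8OX1, which encodes an enzyme of abscisic acid breakdown, had the value 1.55 ± 0.12 (adjusted p = 0.0643), CAB1R 0.90 ± 0.13 (adjusted p = 0.0995) and CHS1 -0.94 ± 0.12 (adjusted p = 0.0917).

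Over all probes limma called 10 between 24 h and 6 h, 8 higher and 2 lower, 7 of them with 1 gene. LOC4337274 rose by 2.02 ± 0.13 and LOC4345968 by 1.92 ± 0.11, and LOC9272107 fell by 2.04 (SE 0.12). Leaving out any 1 of the 6 arrays left 0 calls, with 3814 to 7776 probes at an unadjusted p under 0.05, and the count was 217 at an adjusted p of 0.10 (133 higher and 84 lower), 2364 with a trended and robust prior (1247 and 1117) and 1379 over the brighter probes (694 and 685). Without 24 h replicate 1 the WRKY, dehydration and photosynthesis lists had adjusted p of 0.0655, 0.0655 and 0.0508, and without one 6 h array each call was also lost, at 0.181 without replicate 2 for WRKY, 0.290 without replicate 1 for dehydration and 0.103 without replicate 2 for photosynthesis. The WRKY call was also lost over the brighter probes, where its mean was 0.30 (adjusted p = 0.089).

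The 2 comparisons with 0 h shared calls. CYP701A8, CPS2 and LAC19 rose in both. Called in both and in the same direction were 68 probes, 43 higher and 25 lower, against 0.604 and 0.514 expected of independent lists, which leaves out the shared controls. In opposite directions 1 probe was called in both, that of LOC4342395, named after its values were seen, which fell by 0.69 at 6 h (SE 0.10, adjusted p = 0.0394) and rose by 0.94 ± 0.10 at 24 h (adjusted p = 0.0449). Simulated unchanged groups gave 0 calls in either comparison, so they give no chance value for this overlap. Of the 699 probes called at 6 h, 658 (94.1%) had a 24 h change of the same sign, with a median ratio of the 24 h to the 6 h change of 0.516. Simulations with the 6 h changes and no 24 h effect gave 66.97% of the same sign and a median ratio of 0.0844, at most 0.0961. Fold changes of all probes correlated with r = 0.591, against 0.499 in simulations of unchanged groups. Their covariance was 0.0564 against a simulated 0.0229, a difference of 0.0335. The simulations gave every group the pooled spread, whereas differences within pairs had an SD of 0.270 at 0 h, 0.357 at 6 h and 0.274 at 24 h. The simulated values are therefore not those of the control pair's own, smaller spread, and the size of the difference is approximate. Both comparisons used the same 2 control arrays, too few to give each comparison a pair of its own. Part of the excess of shared calls may therefore come from the shared controls.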

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

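The tests of time of day and of handling were chosen after the results were seen, and those of intensity before their own values were seen. With 2 arrays per group no array was tested as lying apart from its group.

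The effects at 24 h and 6 h, both against 0 h, differed for 10 probes when their difference was tested with limma. The values of 24 h minus 6 h were 2.02 for LOC4337274, 1.92 for LOC4345968, 1.88 for LOC4337484, 1.63 for LOC4342395, 1.60 for LOC4347775 and 1.49 for LOC4334644. They were 1.91 for probe 16561018 and 1.47 for probe 16472254, and -2.04 for LOC9272107 and -2.38 for probe 16427159. LOC4345968 was at -2.82 at 6 h and -0.90 at 24 h against 0 h, and probe 16427159 at 2.60 and 0.22. Of the lists, photosynthesis differed by 0.40, abscisic acid and dehydration by 0.36 and WRKY by 0.33 with a preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.588 for each), and no member passed over all probes. That version called a simulated shift of 0.7 in the diterpenoid list in 0% of draws for 24 h against 6 h. The simulation drew genes independently and shifted the diterpenoid list alone. The photosynthesis, dehydration and WRKY lists had estimated correlations of 0.114, 0.148 and 0.318, so it cannot tell whether correlation accounts for their lost calls.

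The first pattern is the rise of the diterpenoid phytoalexin list at 6 h and 24 h. Time of day as the whole cause predicts no change a whole day after 0 h, if both times fell at the same hour of the day. The mean change at 24 h was 0.737 (SE over genes 0.164). A bias that follows intensity predicts a mean among those of random lists matched on mean expression. The list lay at the 100th percentile of 10000 such lists at 6 h and the 99.99th at 24 h. The random lists had mean changes of 0.0421 and 0.0336, far below those of the list. The list was chosen for its change and the random genes were drawn independently, so the percentiles do not measure chance. The number of arrays from plants handled or kept as long without yeast is 0, so yeast, handling or elapsed time without yeast cannot be told apart. A response to the yeast is therefore a hypothesis that may be true and was not separated from handling.

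The second pattern is the fall of the clock and photosynthesis lists at 6 h. Random lists matched on mean expression had mean changes of 0.0101 for the clock and 0.0072 for photosynthesis, which argues against intensity bias. The lists lay at percentiles 0.1 and 0.05 among them. These percentiles do not measure chance, for the same reasons as above. For photosynthesis the mean change at 24 h was -0.099 (SE over genes 0.0692), within 2 SE of 0. Time of day is a candidate explanation for most of that fall, but a response to yeast or handling that had passed by 24 h predicts the same. The list's array means were still lower at 24 h, 10.50 and 10.47 against 10.59 and 10.57 at 0 h. For the clock the mean at 24 h was -0.301 (SE over genes 0.0974), with array means of 10.76 and 10.75 at 0 h and 10.45 and 10.46 at 24 h. These values argue against time of day as the whole cause only if both times fell at the same hour of the day. The hour of sampling was not used here, and the SE over genes does not measure the spread between plants. Without an array of 0 h or 24 h the mean ran from -0.306 to -0.296, and the 6 h arrays do not enter it. The call at 24 h was lost in each of those fits, which have fewer degrees of freedom. It was also lost by camera with an estimated correlation (adjusted p = 0.494), over the brighter probes (0.0516) and under the replicate block (0.0515). Time of day for part or all of the clock's fall, handling and a response to the yeast stay open.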

How the results depend on the processing

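An adjusted p of 0.10, the count of identical probes once and the simulated covariance of each setting were chosen after seeing the data. No called list or gene past the threshold changed sign. The sign turned for 15 values of named genes that did not pass, in 20 settings, none past the threshold. Without an array, the 6 h values ran from -0.423 to 0.106 for WRKY62, -0.393 to 0.0421 for ACS1, -0.288 to 0.518 for ACS5, -0.0465 to 0.296 for PRX112, -0.01996 to 0.356 for GSTU6, -0.0758 to 0.126 for CEBIP and -0.0572 to 0.253 for Lsi2. Those at 24 h ran from -0.118 to 0.0124 for ACS1 and -0.0395 to 0.303 for PRX112. Those of 24 h against 6 h ran from -0.095 to 0.34 for ACS1, -0.204 to 0.158 for ACS2, -0.12 to 0.268 for GA20OX2, -0.0229 to 0.0619 for GI, -0.113 to 0.127 for PRX112 and -0.168 to 0.142 for Lsi2, and quantile normalization turned Lsi2 to 0.00521. For named genes, a call ended for 3 and began for 3 under quantile normalization, began for 97 over the brighter probes, and ended for 58 under the replicate block. Over the brighter probes 3 list calls ended, those of the pathogenesis-related and clock lists at 24 h and of WRKY between 24 h and 6 h, and the call of the expansin and XTH list at 6 h began (adjusted p = 0.0140). Counts of calls for 6 h, 24 h and 24 h against 6 h were 3369, 3582 and 2364 with a trended and robust prior, 2437, 2458 and 1379 over probes with a mean above the median (fewer, brighter probes), 1673, 1017 and 217 at an adjusted p of 0.10, and 0, 0 and 0 with the 2 groups compared alone (5746, 8238 and 4946 probes at an unadjusted p under 0.05 by limma). A 2-fold minimum gave 362 at 6 h, and a count of nearest arrays at least 2-fold apart with no test gave 279 at 6 h and 78 between 24 h and 6 h. Quantile normalization gave 6 calls between 24 h and 6 h, 4 higher and 2 lower against 8 and 2. The loss of calls and of shared calls without any 1 array came in fits with 2 residual degrees of freedom. The replicate block also leaves 2 and called 37 probes at 6 h, so that number alone does not account for the loss. In simulations with 5 arrays, which left out 1 array of the second group of a comparison, no change was recovered. Shared calls were 993 over the brighter probes. The covariance was 0.0628 over those probes, against 0.0120 in simulations of unchanged groups there. It was 0.075 and 0.0744 without a control array, against 0.0460 with 1 control, and 0.0559 to 0.0569 without another array, against 0.0230. Observed minus simulated was 0.0507 over those probes, 0.0290 and 0.0283 without a control array, and 0.0330 to 0.0339 without another. These simulations also gave every group the pooled spread, so the smaller differences without a control array do not show a smaller excess. No list was called with an estimated correlation (0, 0 and 0), where the clock list had adjusted p = 0.324 at 6 h with its mean of -0.659 and adjusted p = 0.494 at 24 h with its mean of -0.301. Over the brighter probes 1 list was called at 24 h and the clock list at 24 h, at -0.301, was not called. Without an array, 1 to 3 lists were called at 24 h, 0 to 3 between 24 h and 6 h, and the clock mean was -0.306 to -0.296 at 24 h. The cause of changes with the prior was not tested. Signal over background was not used here, so what dim probes limit is open.

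With the replicate number as a block, 37 probes were called at 6 h, 13 higher and 24 lower, 0 at 24 h and 0 between 24 h and 6 h (6178, 6168 and 5296 at an unadjusted p under 0.05), with 0 shared calls. The clock list at 24 h, at -0.301, was not called under the block (adjusted p = 0.0515), and between 24 h and 6 h, at 0.358, it was (adjusted p = 0.0495). Deviations of same-numbered arrays correlated with -0.0841, -0.0013 and 0.0016, so the arrays share only a number.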

Other observations

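The screen of symbol families and its tests were chosen after the data were seen. All 86 families of at least 5 genes that share the start of their symbol were tested with camera. At 6 h against 0 h, 4 families passed, all higher. The germin-like genes GER had a mean log2 change of 0.69 over 6 genes, 6 of them higher (adjusted p = 0.0109). The MCM genes, most of them of the replicative helicase, had 0.62 over 6, all higher (adjusted p = 0.0176). The kinesins had 0.33 over 17, 15 higher (adjusted p = 0.0176), and the cellulose synthases CESA 0.42 over 7, all higher (adjusted p = 0.0181). With an estimated correlation each had adjusted p = 0.916. Single genes past the threshold over all probes were GER5 and KIN14C (0.97 ± 0.13). No MCM or CESA gene passed, and MCM2 had 1.05 ± 0.16 (adjusted p = 0.0511) and CESA5 0.89 ± 0.18 (adjusted p = 0.0896).

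At 24 h against 0 h the germin-like family passed again, with a mean of 0.64 (adjusted p = 0.00568, adjusted p = 0.910 with an estimated correlation), as did the family of 6 ABCG transporters with a mean of 0.66 (adjusted p = 0.0217, adjusted p = 0.910 with an estimated correlation). None of the 6 germin-like genes passed over all probes (adjusted p from 0.0822 to 0.187), and of the ABCG genes ABCG48 alone did. Between 24 h and 6 h the cellulose synthase family passed with a mean of -0.39 and 7 of 7 values below 0 (adjusted p = 0.0077, adjusted p = 0.982 with an estimated correlation). None of its genes passed over all probes (adjusted p from 0.146 to 0.663).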
